A study of Mus musculus with 4 samples.

How the data were processed

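RNA was measured in 4 libraries of mouse iEpiSCs, 2 of genotype c-Jun-/- and 2 wild type. Groups and replicate numbers were taken from the sample titles and genotype labels. Per the labels' protocols, ESCs were grown in 2i and LIF, replated, and after 8 hours given epiblast stem cell medium with XAV939 and IWR-1, with colonies appearing at 4 to 5 days. Total RNA was prepared with TRIzol, libraries with an Illumina TruSeq RNA kit, and sequencing was done on a NextSeq 500, again per the labels' protocols. The labels do not state that the kit kept strand, so a gene cannot be told from an overlapping antisense gene (for example Igf2r or Kcnq1ot1 and their antisense partners).

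The authors deposited 1 RSEM gene table per library. Per the submitters' processing notes, RSEM, Bowtie2 and bcl2fastq were used with genome build mm10. Versions, alignment options, filters and the annotation release are not given in the sources used here. Per the file headers, each table holds the expected count of the gene (an estimated count that need not be whole, since reads shared between genes are split), TPM, FPKM and an effective length in bases, with no normalization between libraries beyond what TPM and FPKM do by definition. Of the expected counts above 0 of a library, 86.2% to 87.1% were exactly whole numbers (92.2% to 92.8% with zeros counted). The deposited FPKM values were looked at and not used in a test. Splitting of shared reads makes the values of near-identical family members uncertain.

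Each table lists 29267 Ensembl gene identifiers, and 28756 of them were matched to a symbol and a position in GENCODE M21 (GRCm38, the same assembly as mm10). Expected counts were rounded to whole numbers. Genes were kept by the default filterByExpr rule of edgeR (minimum count 10, minimum total 15), which left 12598. Libraries were scaled by TMM (factors 0.988 to 1.0085), and the genotypes were compared with edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest, edgeR 4.0.16, R 4.3.3) with no covariate. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. The biological coefficient of variation was 6.5%. CPM values are counts scaled to 1e6 per library, with library sizes scaled by TMM. Intervals of count ratios are exact 95% intervals conditional on the summed counts of both groups, and these intervals and the floor of 3 counts cover counting error only. Within a genotype the libraries differed by more than counting noise (chi-square per degree of freedom 2.51 in knockout and 2.55 in wild type), so none were treated as duplicates. Pearson's r of log2 CPM across genes was 0.981 and 0.982 within genotypes and 0.957 to 0.96 between them. With 2 samples against 2, a permutation of labels cannot reach 0.05, and none was used for the genotype comparison.

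Before the data were examined, 35 gene lists were fixed, covering AP-1, pluripotency, lineage markers, signalling targets, adhesion, chromatin, stress, metabolism and quality. The 30 lists with 5 or more tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, adjusted over those lists. Camera was repeated with an estimated correlation. The rule for named genes was also fixed in advance. It takes the tested AP-1 family members; the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, without predicted, pseudogene or small RNA names; and up to 4 members of each list with the smallest p. Of the genes taken from the lists, those with the smallest p are given. Chosen after their values were seen, to describe a list, were Fgf5, Nanog, Pou5f1, Klf2, Nodal, Tdgf1, Foxh1, Dusp4 and Axin2. Fgf17, Nkx1-2, Mixl1, Sp5, T, Col1a1, Col1a2, Itgb1, Slc2a1 and Cdkn1a were chosen in the same way. So were Esrrb, Klf4, Tfcp2l1, Tet2, Fgf4, Dppa5a, Zfp42, Nr0b1, Prdm14, Dppa3, Tcl1, Egr1, Ccnd1 and Vegfa. The same holds for the genes named only in the closing observations, except Mafk, Maff, Atf7, Ring1, Hist4h4 and Igf2, which the rule named.

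Alternatives fixed in advance were RLE scaling, total counts without TMM, DESeq2 1.42.0, limma voom, limma with a trend on log2(TPM + 1), no filter beyond a count above 0, a filter of 1 CPM in 2 libraries, the replicate number as a block, effective length offsets, a test against a log2 fold change of 1 (glmTreat), fry, and leaving out each library in turn. Fits without chromosome 8 genes, or with these genes centred by an offset in the knockout libraries, were added after the data were seen.

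The pipeline was tested on simulated counts drawn at the real means and library sizes for this comparison. Without a chromosome 8 shift (12383 genes tested), genes changed by a log2 of 0.585 and 1 were called in the right direction in 52% and 73% of cases, and 7.4% of calls were unchanged genes. With a simulated chromosome 8 shift (12401 genes tested), 63.3% and 81.4% of changed genes were called, and 4.4% of calls were unchanged genes. The changed genes were drawn anew for each simulation. The simulations made 135 and 566 calls in all, fewer than the 1956 of the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.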

Results

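The series measured messenger RNA in mouse induced epiblast stem cells (iEpiSCs) with and without c-Jun, a subunit of the AP-1 transcription factor. Epiblast stem cells hold the primed form of pluripotency, that of the epiblast after implantation. The iEpiSCs were derived from naive embryonic stem cells (ESCs) in medium with 20 ng/ml Activin A and 20 ng/ml bFGF. During the conversion the medium also held 2 µM XAV939 and 2.5 µM IWR-1, inhibitors of canonical Wnt signalling. Of the 4 libraries, 2 came from cells of genotype c-Jun-/- and 2 from wild-type cells. Within each genotype the libraries carry the replicate numbers 2 and 3. Total expected counts were 6341342 and 4666559 in knockout replicates 2 and 3, and 5027635 and 5339937 in wild-type replicates 2 and 3. A count of 3, the limit that a count of 0 allows, corresponded to 0.473 to 0.643 CPM (counts scaled to 1e6 per library). The labels do not say whether replicates were separate cultures or clones, so p-values measure only the spread between these samples. Genotype is not separable from cell line here, so a difference between the genotypes need not come from the loss of Jun. Unless stated otherwise, fold changes are log2 ratios of knockout over wild type with n = 2 per genotype and ± gives the standard error. The study's title places the work in chromatin architecture of primed cells, and the comparison made here asks which transcripts differ between iEpiSCs of the 2 genotypes.

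Jun itself was lower in both knockout libraries. Jun (ENSMUSG00000052684, a protein-coding gene on the minus strand of chromosome 4 from 95049034 to 95052222, GRCm38) had 28.9 and 29.6 CPM in the knockout libraries. The wild-type libraries had 106 and 121 CPM. Its log2 fold change was -1.96 ± 0.12, a level 3.89-fold higher in wild type (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.83e-13). Transcript assigned to Jun thus remained in the knockout libraries, with 182 and 136 counts. The part of the gene removed by the mutation is not given in the sources used here. Among the 14 tested members of the AP-1 family list, 2 were higher, 1 (Jun) was lower and 11 did not pass the threshold (3 higher and 3 lower when adjusted over the list alone). Jund rose by 0.86 ± 0.07 (edgeR adjusted p = 2.54e-10), from 147 ± 6.42 to 268 ± 2.6 CPM (mean ± SD). Junb was higher by 0.45 ± 0.13 (edgeR adjusted p = 0.0153), and its call was lost without knockout replicate 3 (adjusted p = 0.111) or wild-type replicate 3 (adjusted p = 0.126; 0.00446 to 0.824 over all alternatives). Jund and Junb both lie on chromosome 8, whose genes were higher as a body in the knockout (values below). With chromosome 8 genes centred on their own median, an alternative chosen after the data were seen, Junb stood at -0.065 and Jund kept its call at 0.35 (edgeR adjusted p = 0.00117). Fos (-0.11 ± 0.32), Fosb (0.85 ± 0.60), Atf3 (0.34 ± 0.27) and Atf4 (0.18 ± 0.07) did not pass the threshold, nor did Fosl2 at -0.71 ± 0.27 (edgeR adjusted p = 0.0744) or Maf at -1.18 ± 0.43 (0.0634). Maf, on chromosome 8, passed with that chromosome centred (-1.69, edgeR adjusted p = 0.00723). Without knockout replicate 3, Fosl2 and Maf both passed (edgeR adjusted p = 0.00457 and 0.00174), the lowest values over the alternatives, against highest values of 0.6 and 0.551. The AP-1 family list as a whole showed no shift in a common direction against other genes (camera adjusted p = 0.845).

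**Figure D1:**
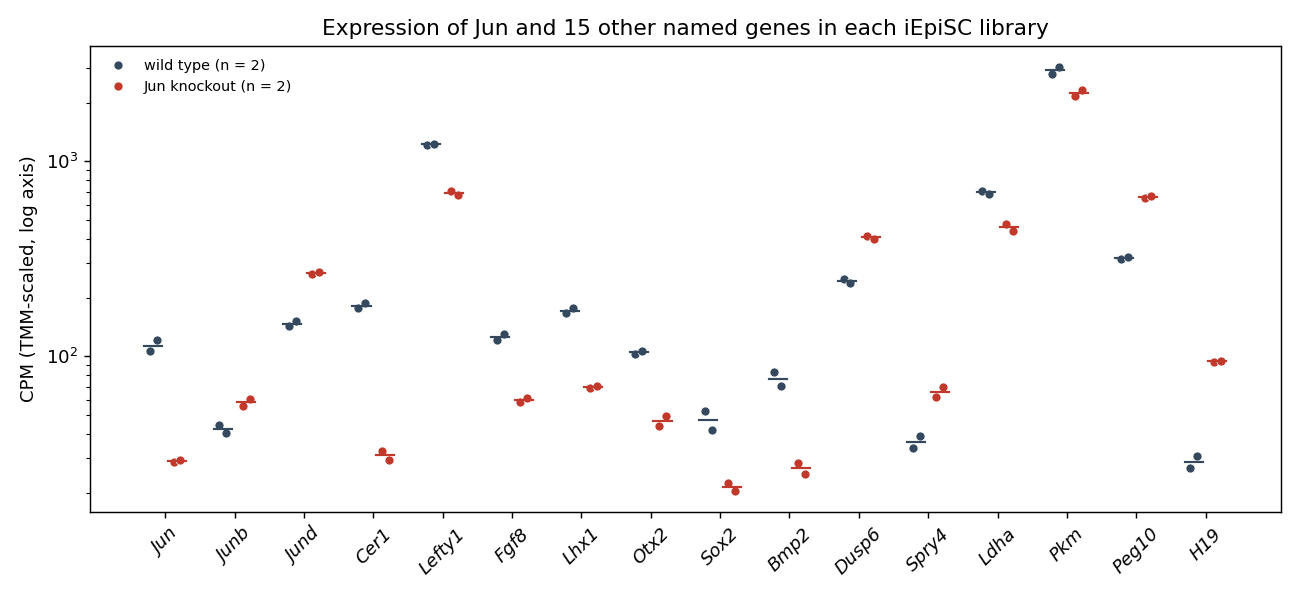
Expression in CPM (log axis) of Jun and 15 other genes in each library, with wild-type libraries in dark blue and knockout libraries in red; points are libraries (n = 2 per genotype) and short lines their means. Jun stood at 28.9 and 29.6 CPM in the knockout libraries against 106 and 121 CPM in wild type. For all 16 genes the libraries of the genotypes did not overlap. The genes were picked among named genes past the adjusted p threshold, so this lack of overlap follows largely from the choice.

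Across the transcriptome, 12598 genes passed the filter on low counts. Of these, 1034 were higher and 922 were lower in the knockout at an adjusted p under 0.05 (edgeR quasi-likelihood test). The log2 fold change was 1 or more for 251 of the higher genes and -1 or less for 227 of the lower genes. The higher genes were not spread evenly over the genome. Chromosome 8 held 5.43% of the tested genes but 37.8% of the higher ones: 391 of its 684 tested genes were higher and 7 were lower. The median log2 fold change on chromosome 8 was 0.51, while the medians of the other autosomes lay between -0.03 and 0.01. Chromosome 8 took 6.27% and 6.32% of the counts in the knockout libraries and 4.45% and 4.48% in the wild-type libraries. The shift was present in each of the 4 knockout and wild-type library pairs (0.499 to 0.535) and near 0 between libraries of the same genotype (-0.013 and -0.005). Over 10 Mb bins with 20 or more tested genes the median lay between 0.476 and 0.551. The bin from 50 to 60 Mb, with 11 genes, had 0.753. Outside chromosome 8, 643 genes were higher and 915 lower. A fit without chromosome 8 genes, chosen after the data were seen, gave 673 higher and 797 lower genes. Members of a list that lie on chromosome 8 are named as such in what follows.

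**Figure D2:**
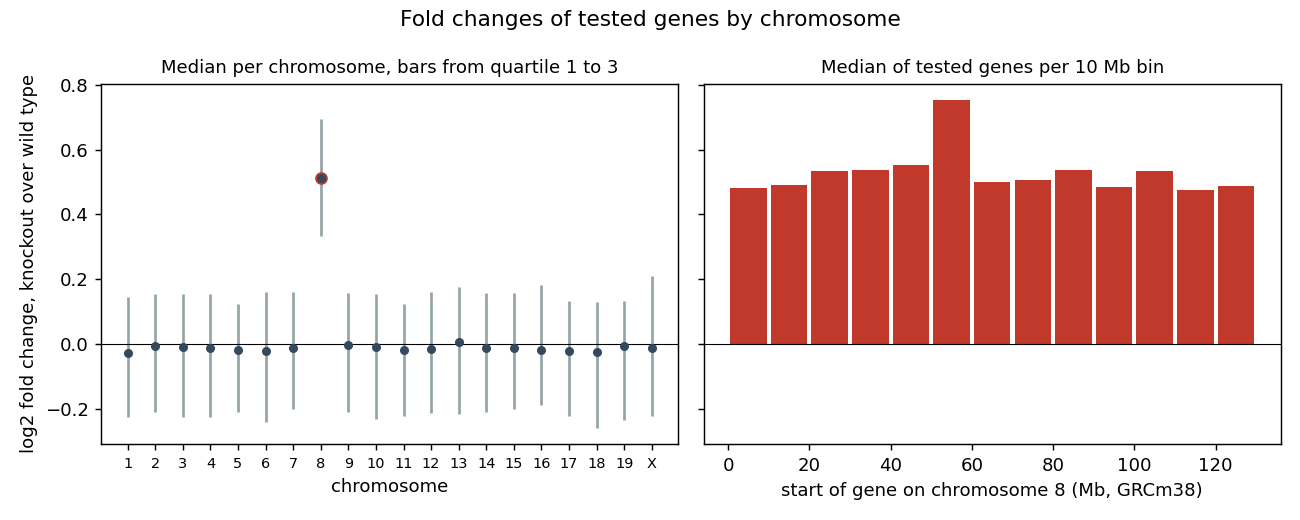
Left, median log2 fold change (knockout over wild type) of the tested genes on each chromosome, with bars from the lower to the upper quartile; right, the median in 10 Mb bins along chromosome 8 (GRCm38). Chromosome 8 stands at 0.51 while the other autosomes lie between -0.03 and 0.01, and every bin of chromosome 8 lies at 0.476 or above.

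Most of the 10 largest increases among genes with a mean of at least 5 CPM were of transcripts below 2 CPM in wild type. Parp12, an ADP-ribosyltransferase, had 14.0 and 18.5 CPM in the knockout libraries and 1 count over both wild-type libraries, a ratio of 165 (95% counting interval 29.3 to 6570). Klhl22, an adaptor of cullin ubiquitin ligases, rose from 1.16 to 42.8 CPM (log2 fold change 5.18 ± 0.30, edgeR adjusted p = 3.49e-14). Trim25 (4.86 ± 0.49), the meiosis gene M1ap (4.04 ± 0.55), the nucleosome-binding protein gene Hmgn3 (3.84 ± 0.53), Npepl1 (4.29 ± 0.57), Cnn1 (3.23 ± 0.46) and the lysosomal enzyme gene Gusb (3.15 ± 0.36) followed, with edgeR adjusted p between 3.49e-14 and 2.86e-06 for these and Klhl22. Tex15, a germ cell gene on chromosome 8, rose by 3.67 ± 0.19 (edgeR adjusted p = 3.57e-15), from 5.27 to 67.7 CPM, and by 3.16 with chromosome 8 centred. The Y-linked Eif2s3y rose by 4.59 ± 0.35. Without wild-type replicate 2 the log2 fold changes of Klhl22 and Eif2s3y were 5.79 and 5.60, and without wild-type replicate 3 those of Eif2s3y and Gusb were 3.98 and 3.84. The largest decreases among genes with a mean of at least 5 CPM were those of Xlr3b (-3.57 ± 0.34), Scel (-3.47 ± 0.53), Cyp2j6 (-3.37 ± 0.33), the ETS factor gene Ehf (-2.87 ± 0.46), Myh4 (-2.70 ± 0.41) and the imprinted Asb4 (-2.65 ± 0.17). Cer1, which encodes a secreted antagonist of Nodal, BMP and Wnt ligands, fell by 2.54 on the log2 scale (± 0.11, edgeR adjusted p = 1.63e-17), from 182 ± 7.97 to 31.2 ± 2.3 CPM (mean ± SD). Ryr2 (-2.51 ± 0.46), Naip6 (-2.46 ± 0.46) and Cfc1 (-2.37 ± 0.39), a co-receptor of Nodal, followed. Scel had 12 and 0 counts in the knockout libraries, and its log2 fold change was -8.93 without knockout replicate 2 and -2.66 without knockout replicate 3. Without knockout replicate 2 the log2 fold changes of Cyp2j6, Ehf and Myh4 were -3.98, -3.98 and -3.55. With DESeq2 Scel did not pass (adjusted p = 0.295; 1.89e-13 to 0.295 over the alternatives). Xlr3b, Naip6, Cyp2j6 and Myh4 belong to families of near-identical or clustered copies, among which reads can be split, and their values are uncertain for that reason. That the genotypes did not overlap was part of the rule by which these genes were chosen, and chance gives it to 1 in 3 genes with 2 libraries against 2.

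Of 23 tested primed epiblast genes, 13 fell, none rose and 10 did not pass the threshold (14 lower and 1 higher when adjusted over the list alone). Besides Cer1, these included Otx2, a transcription factor of the epiblast (-1.18 ± 0.11, edgeR adjusted p = 1.91e-09), the N-cadherin gene Cdh2 (-0.58 ± 0.08) and Sfrp1 (-0.76 ± 0.10), which fell although it lies on chromosome 8. Fgf5, another primed marker, was among the 13 at -0.33 ± 0.07. The list differed from other genes (camera adjusted p = 6.04e-10), a call lost with an estimated correlation (adjusted p = 0.241). Of 12 tested naive pluripotency genes, 6 rose and 6 did not pass (also 6 when adjusted over the list alone). Dppa4 and Tbx3 had 37 and 32 counts over the knockout libraries and 0 over the wild-type libraries, which puts them at least 11.8-fold and 10.2-fold higher against a floor of 3 counts over the wild-type group. Dppa2 rose by 3.24 ± 0.64 (edgeR adjusted p = 0.00034). Klf5 was called at 0.56 ± 0.17 (edgeR adjusted p = 0.0253), but not without knockout replicate 2 (0.124) or wild-type replicate 2 (0.307). Klf2, on chromosome 8, was called at 1.05 ± 0.34 (edgeR adjusted p = 0.0353) but lost its call without any of the 4 libraries (0.0612 to 0.185) and with chromosome 8 centred (0.368). The 6 that did not pass were Nanog (-0.15 ± 0.09), Esrrb (-0.12 ± 0.34), Klf4 (0.07 ± 0.52), Tfcp2l1 (0.44 ± 0.47), Tet2 (0.11 ± 0.20) and Fgf4 (0.064 ± 0.505). Of the 6 that rose, Dppa4, Tbx3, Dppa2 and Dppa5a had means of only 2.65 to 5.59 CPM in the knockout. Zfp42, Nr0b1, Prdm14, Dppa3 and Tcl1, naive markers of the same list, were below the filter on low counts. They had 0 counts in every library, except 1 count of Zfp42 in knockout replicate 2. The naive list had a camera adjusted p of 0.0143 and an adjusted p = 0.323 with an estimated correlation. Its call was lost without knockout replicate 2 (camera adjusted p = 0.16) or wild-type replicate 3 (0.0679), and its values over the alternatives ran from 0.00142 to 0.16. With Dppa4 and Tbx3 at their bounds the mean of the list was 1.24 in place of 1.84, while the median, which both genes exceed either way, was 0.499. Core pluripotency factors went both ways. Of 12 tested, 5 rose and 2 fell (5 and 3 when adjusted over the list alone), with Sox2 at -1.14 ± 0.16 (edgeR adjusted p = 3.55e-06) and Sall4 at -0.41 ± 0.07, while Utf1 rose by 0.36 ± 0.07 and L1td1 by 0.22 ± 0.06. Pou5f1, which encodes Oct4, was called at 0.21 (edgeR adjusted p = 0.0116), but not without knockout replicate 3 (0.0758) or wild-type replicate 3 (0.0541). The core list showed no shift in a common direction against other genes (camera adjusted p = 0.976, direction up, against a median of -0.02 and a mean of -0.04). Members that move both ways can cancel in such a test.

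Activin A and bFGF of the medium act through the Nodal and Activin and the FGF and ERK pathways. Of 16 tested Nodal and Activin targets, 7 fell, none rose and 9 did not pass (the same numbers when adjusted over the list alone). Lefty1, an inhibitor of Nodal that Nodal itself induces, fell by 0.83 on the log2 scale (± 0.05, edgeR adjusted p = 5.17e-14), and Fgf8 (-1.08 ± 0.10) and Pmepa1 (-0.84 ± 0.08) fell with it and with Cer1. The camera adjusted p was 7.25e-13 for this list and 0.241 with an estimated correlation (adjusted p). Nodal, Tdgf1 and Foxh1, which encode the ligand, its co-receptor and a nuclear partner of SMADs, did not pass the threshold. Of 18 tested FGF and ERK targets, 8 rose, 1 fell and 9 did not pass (the same when adjusted over the list alone). Dusp6, a phosphatase of ERK, rose by 0.74 ± 0.06 (edgeR adjusted p = 2.54e-10), Spry4 by 0.84 ± 0.13, Etv4 by 0.56 ± 0.08 and Etv5 by 0.45 ± 0.07. The exception was Dusp4, on chromosome 8, at -0.38 ± 0.09, whose call was lost without knockout replicate 2 (edgeR adjusted p = 0.0568). The list had a camera adjusted p of 2.45e-04, and an adjusted p = 0.241 with an estimated correlation. Of 13 tested BMP targets and components, 4 fell and none rose (5 and 1 when adjusted over the list alone). Bmp2 fell by 1.51 on the log2 scale (± 0.14, edgeR adjusted p = 8.08e-10), from 76.8 to 26.7 CPM, and Id3 (-0.75 ± 0.15) and Smad6 (-0.99 ± 0.24) also fell. The camera adjusted p was 0.0143, with an adjusted p = 0.323 under an estimated correlation and 0.128 by camera without knockout replicate 3 (0.00564 to 0.128 over the alternatives). Wnt targets, whose pathway the conversion medium inhibited, went both ways: of 15 tested, 3 rose and 5 fell (the same when adjusted over the list alone), among them Lgr5 at -1.34 ± 0.14 (edgeR adjusted p = 6.22e-09) and Dkk1 at -0.75 ± 0.13. Axin2 did not pass (0.20 ± 0.11). The Wnt list showed no shift in a common direction against other genes (camera adjusted p = 0.325). Nkd1, called at 0.51 ± 0.12, lies on chromosome 8 and stood at -0.006 with that chromosome centred.

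**Figure D3:**
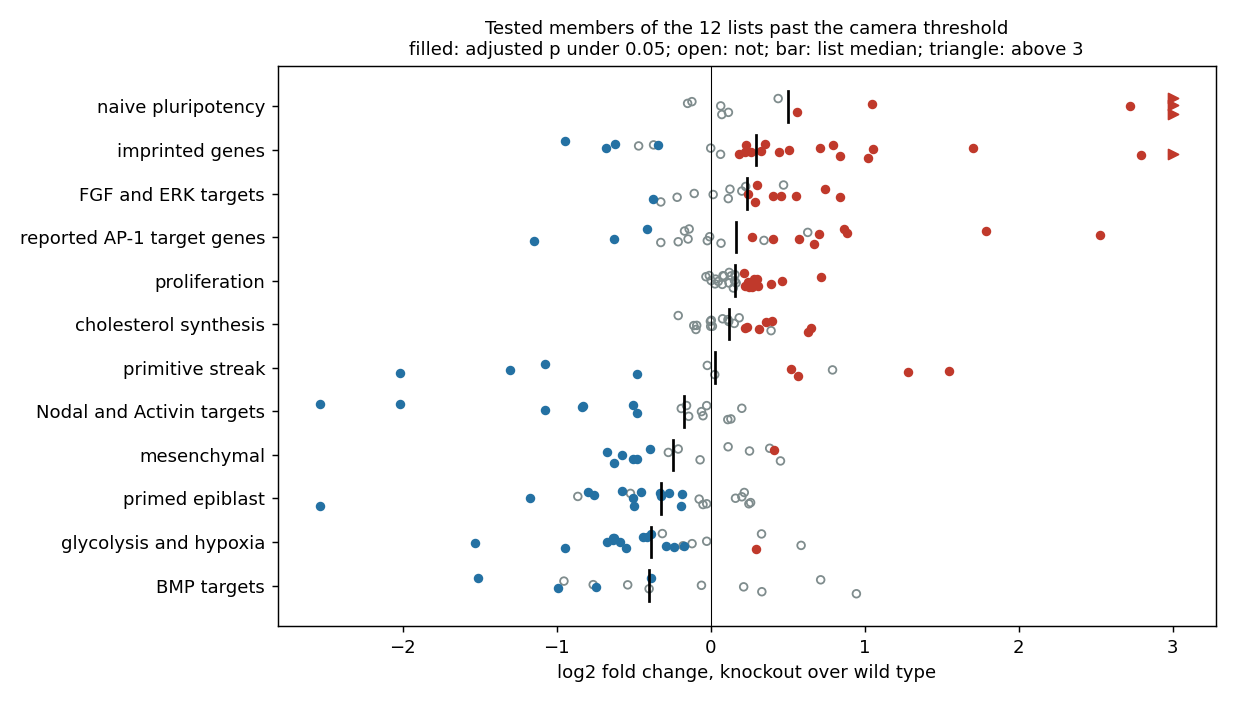
Log2 fold change (knockout over wild type) of each tested member of the 12 gene lists past the camera threshold; filled points passed the adjusted p threshold of 0.05 in the edgeR test (red higher, blue lower), open points did not, black bars are list medians, and 4 members above 3 are drawn as triangles at 3. Members of the Nodal and Activin list that passed lie below 0 in all 7 cases, and those of the naive list above 0 in all 6.

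Lineage markers moved in part. Of 11 tested primitive streak genes, 4 rose and 4 fell (the same when adjusted over the list alone). The organizer genes Lhx1 (-1.30 ± 0.09, edgeR adjusted p = 3.44e-12) and Gsc (-2.02 ± 0.28) fell, as did Fgf8 and Eomes (-0.48 ± 0.10), while Fgf17 (1.55 ± 0.36), Nkx1-2 (1.28), Mixl1 (0.56) and Sp5 (0.52) rose. Without knockout replicate 2 the calls of Nkx1-2, Mixl1 and Sp5 were lost (edgeR adjusted p = 0.0626, 0.261 and 0.184), and that of Mixl1 also without wild-type replicate 3 (0.165). The log2 fold change of Gsc was -2.63 without knockout replicate 2. T (Brachyury) did not pass (0.03 ± 0.05). Camera placed this list down (adjusted p = 0.0465) although its median was 0.03 and its mean -0.02, with an adjusted p = 0.397 under an estimated correlation. Its call was lost without knockout replicate 3 (camera adjusted p = 0.134) or wild-type replicate 3 (0.0697), and when chromosome 8 genes were left out (0.0618), and it was kept in 5 of 13 alternatives (0.0429 to 0.958). Of 12 tested definitive endoderm genes, 1 rose and 5 fell (1 and 6 over the list alone): Trh, the precursor of thyrotropin-releasing hormone, rose from 178 ± 6.37 to 641 ± 4.68 CPM (mean ± SD; log2 fold change 1.85 ± 0.06, edgeR adjusted p = 6.19e-20), whereas Sox17 (-1.24 ± 0.22), Cpm (-0.71 ± 0.13) and Cxcr4 (-0.99 ± 0.20) fell (camera adjusted p = 0.833 for the list). Of 11 tested extraembryonic endoderm genes, 2 rose and 4 fell (3 and 7 over the list alone), with Sparc at -0.48 ± 0.06, Apoe at 0.67 ± 0.10 and Lamb1 at -0.29 ± 0.07 (list camera adjusted p = 0.247). The other gene that rose, Col4a1, lies on chromosome 8, stood at -0.093 with that chromosome centred, and lost its call without knockout replicate 3 (edgeR adjusted p = 0.0551). Of 10 tested neuroectoderm genes, 4 rose and 1 fell (the same over the list alone), and 3 of these lie on chromosome 8: Tubb3 rose by 2.13 ± 0.48, Sox1 rose from 8.11 to 19.3 CPM and Irx3 stood at -0.91 ± 0.17. With chromosome 8 centred the call of Sox1 was lost (edgeR adjusted p = 0.0546), and Tubb3 and Irx3 stood at 1.62 and -1.43. Zic1, on chromosome 9, was called at 1.33 ± 0.33, but not without knockout replicate 2 (edgeR adjusted p = 0.0707). The list did not pass (camera adjusted p = 0.247). In the mesoderm list 1 of 7 tested genes passed, Tbx1 at -1.57 ± 0.53 (edgeR adjusted p = 0.0385), a call lost without knockout replicate 2 (0.122) or wild-type replicate 2 (0.884, log2 fold change -0.31), while without wild-type replicate 3 the fold change was -2.24. Pdgfra did not pass (edgeR adjusted p = 0.0911; list camera adjusted p = 0.772; 1 lower over the list alone). Of 10 tested neural crest and surface ectoderm genes 1 fell, Foxd3 at -0.80 ± 0.18, and none rose (2 higher and 1 lower over the list alone; camera adjusted p = 0.946). Of 9 tested trophoblast genes 2 rose and 1 fell (3 and 1 over the list alone), with the imprinted H19 at 1.71 ± 0.13 and Krt7 at -1.01 ± 0.17. The median of that list was -0.37, its mean 0.03 and its camera direction up (adjusted p = 0.433).

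Of 14 tested mesenchymal genes, 6 fell, 1 rose and 7 did not pass (the same over the list alone). Fibronectin (Fn1) fell by 0.50 on the log2 scale (± 0.04, edgeR adjusted p = 5e-10), from 1668 ± 72.6 to 1177 ± 10.1 CPM (mean ± SD), and Sparc and Cdh2 fell with it, while vimentin (Vim) rose by 0.41 ± 0.06. The list had a camera adjusted p of 0.00828, and an adjusted p = 0.397 with an estimated correlation. Its camera call was lost without knockout replicate 3 (0.065) or wild-type replicate 3 (0.0742), and its values over the alternatives ran from 0.000823 to 0.135. Of 23 tested epithelial genes, 2 rose and 4 fell (the same over the list alone), with the keratin genes Krt18 at -0.47 ± 0.07 and Krt8 at -0.36 ± 0.06 and the claudin gene Cldn6 at -0.51 ± 0.07. E-cadherin (Cdh1), on chromosome 8, was called at 0.40 ± 0.05 (edgeR adjusted p = 8.76e-08) and stood at -0.117 with chromosome 8 centred (list camera adjusted p = 0.247). Of 32 tested matrix and integrin genes, 9 rose and 9 fell (9 and 10 over the list alone), and 2 of those that rose, Col4a1 and Itgb1, lie on chromosome 8. With that chromosome centred they stood at -0.093 and -0.191, the latter past the threshold as lower (edgeR adjusted p = 0.0156). Nid2 rose by 0.54 ± 0.07 (edgeR adjusted p = 5.77e-07), while Itgb4 stood at -0.88 ± 0.12 (list camera adjusted p = 0.583). Of 11 tested fibroblast and feeder markers, 1 rose and 5 fell (2 and 6 over the list alone). Fbln2 (-0.93 ± 0.15) and Postn (-1.28 ± 0.24) fell and Col3a1 rose by 3.58 ± 0.66, from 0.478 to 5.93 CPM (list camera adjusted p = 0.136). Col1a1 and Col1a2, the most common collagens of fibroblasts, did not pass (-0.10 and 0.21).

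Genes for architectural proteins of chromatin changed little. Of 30 tested genes for cohesin, CTCF, condensin and lamins, 3 were higher, 1 was lower and 26 did not pass the threshold (3 higher and none lower over the list alone). Mau2, a cohesin loader, and Ctcf were higher by 0.47 ± 0.09 and 0.38 ± 0.08 (edgeR adjusted p = 4.29e-04 and 6.99e-04). Both lie on chromosome 8, and with that chromosome centred they stood at -0.043 and -0.135. The lamin gene Lmnb1 was called at 0.23 ± 0.07 (edgeR adjusted p = 0.0239), but not without knockout replicate 2 (0.301) or wild-type replicate 2 (0.148). Ldb1 was called at -0.24 ± 0.08 (edgeR adjusted p = 0.0489), but not without knockout replicate 2 (0.239), knockout replicate 3 (0.0959) or wild-type replicate 3 (0.356). The list showed no shift in a common direction against other genes (camera adjusted p = 0.143). Of 31 tested chromatin remodelling and Polycomb genes, Kdm6b, an H3K27 demethylase gene, fell by 0.40 on the log2 scale (± 0.06, edgeR adjusted p = 9.46e-06) and 30 did not pass (also 1 lower over the list alone). Suz12 stood at 0.20 ± 0.07 and Eed at 0.29 ± 0.12 (list camera adjusted p = 0.978). Of 14 tested DNA methylation genes, 4 rose and 1 fell (6 and 2 over the list alone), led by the methyl-CpG binding protein gene Mbd1 at 1.38 ± 0.26 (edgeR adjusted p = 1.85e-04), with Uhrf1 at 0.27 ± 0.07. Dnmt3b was called at -0.19 ± 0.05, but not without knockout replicate 2 (edgeR adjusted p = 0.0596). The list had a camera adjusted p of 0.247.

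Glycolysis genes were lower, and genes of proliferation and cholesterol synthesis were higher, in part of each list. Of 21 tested glycolysis and hypoxia genes, 14 fell and 1, the glucose transporter gene Slc2a1, rose (16 and 2 over the list alone). Lactate dehydrogenase A (Ldha) was at -0.59 ± 0.06 (edgeR adjusted p = 1.81e-09), Slc2a3 at -0.64 ± 0.07, Pgk1 at -0.55 ± 0.06 and Pkm at -0.39 ± 0.04. The list differed from other genes (camera adjusted p = 1.26e-11, and adjusted p = 0.241 with an estimated correlation). Of 27 tested proliferation genes, 11 rose and none fell (12 and none over the list alone), with Rrm2 at 0.46 ± 0.09 (edgeR adjusted p = 2.86e-04), Mcm3 at 0.30 ± 0.07 and Mcm5, on chromosome 8, at 0.72 ± 0.07 (camera adjusted p = 1.65e-04, and adjusted p = 0.241 with an estimated correlation). Of 21 tested cholesterol synthesis genes, 7 rose and none fell (9 and none over the list alone). Msmo1 (0.63 ± 0.07) and Mvd (0.65 ± 0.11) lie on chromosome 8, while Fdps (0.36 ± 0.07, edgeR adjusted p = 3.59e-04) does not. With chromosome 8 centred the calls of Msmo1 and Mvd were lost (0.12 and 0.14, edgeR adjusted p = 0.353 and 0.5) and Mcm5 stood at 0.20 (edgeR adjusted p = 0.0478). The camera adjusted p of the cholesterol list was 0.00828, and the adjusted p = 0.323 with an estimated correlation. Textbook AP-1 target genes were higher more often than lower: of 22 tested, 9 rose and 3 fell (the same over the list alone). S100a6 rose by 2.53 ± 0.42 (edgeR adjusted p = 3.58e-05) and Itga5 stood at -0.63 ± 0.12, while Ier2 (0.88 ± 0.09) and Hmox1 (0.67 ± 0.11) lie on chromosome 8. With that chromosome centred Ier2 stood at 0.37 and the call of Hmox1 was lost (0.16, edgeR adjusted p = 0.4). The camera adjusted p of the AP-1 target list was 0.0295, with an adjusted p = 0.479 under an estimated correlation, 0.131 when chromosome 8 genes were left out and 0.0544 without wild-type replicate 2 (0.017 to 0.131 over the alternatives).

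Stress and interferon lists showed no shift in a common direction against other genes. Of 19 tested p53 targets, 3 rose and 3 fell (the same over the list alone), with Aen at -0.53 ± 0.07 (edgeR adjusted p = 3.16e-06), and Cdkn1a at -0.01 did not pass (list camera adjusted p = 0.938). Of 18 tested unfolded protein and integrated stress response genes, 2 rose and 1 fell (the same over the list alone), with Ddit4 at -0.50 ± 0.08 and Herpud1, on chromosome 8, at 0.76 ± 0.17 (list camera adjusted p = 0.325). Of 19 tested interferon response genes, 3 rose and 2 fell (4 and 3 over the list alone), with Ifitm3 at 1.24 ± 0.10 (edgeR adjusted p = 6.42e-11), Tapbp at -0.48 ± 0.07 and Bst2, on chromosome 8, at 0.67 ± 0.11 (list camera adjusted p = 0.696). With chromosome 8 centred the calls of Herpud1 and Bst2 were lost (0.25 and 0.16, edgeR adjusted p = 0.416 and 0.425). Members of the Ifitm family are similar in sequence and can share reads.

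Imprinted genes, expressed from the copy of 1 parent, changed more often than not. Of 24 tested, 16 rose, 4 fell and 4 did not pass (the same over the list alone), and none lies on chromosome 8. Peg10 rose by 1.05 ± 0.06 (edgeR adjusted p = 9.96e-15), from 318 to 660 CPM, and H19 by 1.71 ± 0.13 (edgeR adjusted p = 1.11e-11). Igf2r (-0.68 ± 0.08) and Grb10 (-0.62 ± 0.07) fell. The list had a camera adjusted p of 9.65e-06, and an adjusted p = 0.241 with an estimated correlation. Of the 6 sex-linked genes, 3 Y-linked genes were tested and went apart: Eif2s3y rose from 1.17 to 28.6 CPM, Ddx3y fell from 33.1 to 7.56 CPM (-2.13 ± 0.21, edgeR adjusted p = 4.49e-09), and Uty stood at 31.1 and 30 CPM in wild type and knockout (-0.04 ± 0.17). Of the replication-dependent histone genes, whose messages lack a poly(A) tail, 4 were tested and Hist1h2bc was called at -1.01 ± 0.32 (edgeR adjusted p = 0.0253), though not without knockout replicate 3 (0.174) or wild-type replicate 3 (0.227). In the list of genes of 2-cell-like and germ cells, 2 were tested, Prdm1 (-0.32 ± 0.26) and Rhox5 (0.50 ± 0.49), and neither passed. No Hox gene passed the filter on low counts. Mitochondrially encoded genes were not analysed here.

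Across the lists, 12 of 30 passed by camera with the preset correlation. The 12 lists are not independent, since some share called genes. Cer1 is in the primed epiblast list and in the Nodal and Activin list. Gsc, Fgf8 and Eomes are in the primitive streak list and in the Nodal and Activin list. Cdh2 is in the primed epiblast and mesenchymal lists. The AP-1 target list shares Egr1 with the FGF and ERK list and Ccnd1 with the proliferation list. It also shares Itga5 with the mesenchymal list and Vegfa with the glycolysis and hypoxia list. With an estimated correlation 0 passed by camera, 6 had an unadjusted p under 0.05, and the smallest adjusted p was 0.241. This loss cannot tell whether correlation within a list made the calls. With an estimated correlation camera takes its p from the few residual degrees of freedom of 4 libraries, which the preset setting does not. The glycolysis and hypoxia list had an estimated correlation of -0.031, below the preset 0.01. Its unadjusted camera p still went from 8.41e-13 to 0.0159. By fry, which does not compare a list with other genes, 11 passed. The mesenchymal and BMP lists did not pass (fry adjusted p = 0.0735 and 0.0667), and the DNA methylation list did (0.0159). Fry's mixed test counts changes in either direction. Its adjusted p ran from 0.00332 to 0.0685 over the 30 lists, with 0.00607 for the core pluripotency list. Only the mesoderm list (0.0685) and the chromatin remodelling and Polycomb list (0.0661) did not pass that test.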

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

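The fits on chromosome 8 were chosen after the data were seen; the other alternatives were fixed before. Jun kept its direction and call under every alternative of the gene test (log2 fold change -2.05 to -1.86; adjusted p = 4.92e-07 against a log2 fold change of 1). The gene counts, 1034 higher and 922 lower, stayed within 1.5 times under RLE scaling, total counts, voom and both filters. Leaving out each library in turn gave 835 to 888 higher and 633 to 757 lower genes, with 9 to 12 lists. A lone library was then assumed to vary like the other group. DESeq2 gave 762 higher and 593 lower. Limma on log2(TPM + 1) gave 250 and 170, and effective length offsets gave 498 and 341; of these, 244 and 166, and 477 and 321, were among the genes called in the main test in the same direction. Against a log2 fold change of 1, 76 and 35 passed. The cause of these drops was not tested, except that the last test asks for a larger change. Without chromosome 8 genes 673 were higher and 797 lower, against 643 and 915 outside chromosome 8 in the main test. Library sizes and TMM factors were computed anew in the fit without these genes. Its median log2 fold change was 0.005, while the medians of the other autosomes in the main test lay between -0.027 and 0.006. How much of the difference in gene counts comes from this scaling was not tested. With chromosome 8 centred 651 were higher and 916 lower, so 41.5% of calls were higher, against 52.9%. Of 30 lists 12 passed, 11 with fry and 0 with an estimated correlation, with or without chromosome 8. Under the preset correlation 10 passed without that chromosome. Both knockout libraries carried the chromosome 8 shift, so leaving its genes out cannot tell whether the shift acts on genes elsewhere.

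The replicate numbers did not pair the samples: same-numbered deviations had a correlation of 0.022 across genes, with 2 pairs and no label that ties them. With the number as a block 1250 genes were higher, 1127 were lower and 11 lists passed; the block gave Jun at -1.95. Among genes named here Fosl2, Maf, Atf4, Suz12 and Ddx3x passed under the block (edgeR adjusted p = 0.0315, 0.0227, 0.0289, 0.0231 and 0.0385). Ring1 passed as well, and the primitive streak list did not (camera adjusted p = 0.289).

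Of 123 named genes past the threshold, 58 kept their call under every alternative in which they had a value; limma on TPM ended 59 of the calls, effective length offsets 29 and leaving out a library 6 to 11. Directions turned as follows, with causes not tested. With chromosome 8 centred, Junb stood at -0.065, Col4a1 at -0.093, Itgb1 at -0.191, Cdh1 at -0.117, Nkd1 at -0.006, Mau2 at -0.043 and Ctcf at -0.135, which follows from the subtraction. Among genes not past the threshold, effective length offsets put Fos at 0.007, Ring1 at 0.065, Uty at 0.049 and Axin2 at -0.011, limma on TPM put Atf7 at -0.035, Ring1 at 0.007 and Axin2 at -0.042, and the fit without chromosome 8 put Cdkn1a at 0.01. Leaving out a library put Mafk between -0.009 and 0.564, Maff between -0.238 and 0.091, Atf7 between -0.037 and 0.087, Uty between -0.214 and 0.099, Hist4h4 between -1.591 and 0.03, Cdkn1a between -0.026 and 0.014 and Foxh1 between -0.025 and 0.26. The primitive streak list turned up by camera on TPM (adjusted p = 0.958; 0.0429 to 0.958 over its 13 alternatives). At 4666559 to 6341342 counts, changes of log2 0.585 (3 copies over 2) were called in 52% of simulated cases without a chromosome 8 shift and 63.3% with it, so smaller changes can go uncalled. The simulations made 135 and 566 calls against 1956 in the data, so the adjusted threshold was stricter there and the percentages may not carry over. They came from separate random draws of 100 and 98 genes, so their difference does not measure an effect of the shift.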

Other observations

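The tests in this part that were chosen after their result was seen are those of the bins of chromosome 8, of imprinted genes and of Y-linked genes and the window scan; the spread and GC tests of chromosome 8 and the sum over germline genes were set before. Outside chromosome 8, 382 windows of 5 Mb with 10 or more tested genes were scanned for an excess of called genes (Fisher's exact test, two-sided, Benjamini-Hochberg over windows; neighbouring genes are not independent). The excess of higher genes passed in 3 windows, and 0 windows passed for lower genes (14 at an unadjusted p under 0.05, windows with a lack of lower genes included). On chromosome 4 from 145 to 150 Mb (GRCm38), 15 of 55 tested genes were higher (adjusted p = 4.93e-05). Most of them are zinc finger genes of a cluster, among them Zfp990 (54.6 to 117 CPM, log2 fold change 1.10 ± 0.11), Zfp992 (1.12 ± 0.20), Zfp985 (1.72 ± 0.33) and Gm13212 (2.87 ± 0.29). In the same window 6 genes were lower. Members of this cluster are similar in sequence and can share reads, so single values are uncertain. On chromosome 11 from 40 to 45 Mb, 6 of 14 were higher (adjusted p = 0.00954), including Pttg1 (2.61 ± 0.37) and Ebf1 (2.56 ± 0.39, and 3.34 without wild-type replicate 3). On chromosome 12 from 20 to 25 Mb, 6 of 19 were higher (adjusted p = 0.0455), most of them without a gene name. Transcripts nearly absent in 1 genotype were mostly absent in wild type: 16 called genes had a mean under 0.5 CPM in wild type and 5 CPM or more in the knockout, and 1 had the reverse.

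Chromosome 8 genes were higher in the knockout along the whole chromosome. The spread of their fold changes was 0.978 times that of other autosomes in matched bins of expression (interquartile range 0.414 against 0.423), which argues against regulation of separate genes, since this would widen it. Genes of other autosomes with the same GC content and transcript length did not shift, and the median difference from them was 0.529, which argues against a GC or length bias. A candidate explanation is an extra copy of chromosome 8 in most cells of the knockout cultures: the lowest median of a bin with 20 or more genes was 0.476, and 3 copies in place of 2 would give 0.585 if expression followed copy number. Whether such a gain came with the loss of Jun or with a single clone or passage is not tested here, and DNA copy number was not analysed here.

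Imprinted genes changed in a way that may follow whether methylation of their control regions silences or permits them. From textbook knowledge, 17 of the 24 tested genes were predicted to rise and 7 to fall with lower DNA methylation at imprinting control regions; of the 20 called, 17 went the predicted way, and the exceptions were Igf2, Dlk1 and Zdbf2. The call of Igf2 was lost without knockout replicate 3 (edgeR adjusted p = 0.363) and without wild-type replicate 2 or 3 (0.179 and 0.108). The first test run compared means and did not pass (difference 0.348, exact permutation p = 0.581, two-sided). The prediction, itself written after the values were seen, named medians only for the outcome that would go against it. After that result the test was repeated on medians, which differed by 0.912 (0.44 against -0.47, exact permutation p = 0.00165, two-sided). Both tests are across genes, which are not independent, and the evidence is weaker for the order in which they were run. Dlk1, which was predicted to fall, weighs most on the means, with 39 counts against 1 (ratio 37.3, counting interval 6.3 to 1510). Whether the chromosome 8 shift acts on these genes stays open: the list had a camera adjusted p of 8.5e-08 without that chromosome, but it has no member there, so leaving it out decides nothing. A set of germline genes that methylation can silence left the idea open. It held 34 genes off chromosome 8 out of 36 listed beforehand, and Tex15 was not in the list. The summed CPM of the 34 genes was 1.4 times as high in the knockout (counting interval 1.3 to 1.51), but 1.12 times without Tdrd5, and most had few counts. Imprinting also differs between stem cell lines, and with genotype and line not separable here a difference of line stays open. DNA methylation itself was not analysed here.

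Of 7 tested genes on chromosome Y, 3 were called higher and 1 lower, and only Eif2s3y, Ddx3y and Uty were examined here. The Y-linked genes Eif2s3y and Ddx3y moved apart by 6.73 on the log2 scale while Uty stood at -0.04. This argues against loss of the Y chromosome in either genotype, since all would fall together. Reads of the Y-linked copy assigned to the X-linked copy could give such values: Eif2s3x was at -0.12 ± 0.06 and Ddx3x at 0.11 ± 0.05, each opposite to its Y-linked partner. In CPM, Eif2s3y rose by 27.4 while the change of Eif2s3x was -36.4, and the change of Ddx3y was -25.5 while Ddx3x rose by 65.2, which is more than reads moved from Ddx3y alone would supply. The log2 fold changes of the sums were -0.03 and 0.06. A first criterion of 2 standard errors was met by both X-linked genes and was then made stricter, to an adjusted p under 0.05, which neither met (edgeR adjusted p = 0.194 and 0.14), so this cannot be told apart from a difference in the Y-linked genes themselves, and a sequence variant between the lines was not tested.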
